A study of Mus musculus with 6 samples.

How the data were processed

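H3.3 ChIP-seq was carried out on HSCs sorted from bone marrow of C57BL/6 mice, per the labels. The 6 libraries were 2 wild-type H3.3 ChIP, 2 HIRA knockout H3.3 ChIP, 1 wild-type input and 1 HIRA knockout input. Deletion was induced with 2 doses of 20 ug of poly(I:C), and cells were sorted 7 days after the first dose, per the labels' protocols. Chromatin was digested with micrococcal nuclease and precipitated with a rat monoclonal antibody to H3.3, per the labels' protocols. The submitters' processing notes name Bowtie2, deepTools, MACS2 and HOMER, without versions, and the genome build mm10.

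The deposited files hold a segmentation of the genome into 18 states in bins of 200 bp, once as a dense and once as an expanded browser track. The names of the deposited files label the map as wild-type HSC H3.3. Per the file headers, the track is named for HSCs and its states were ordered by emission. ChromHMM is named only in the track and file names. The signal tracks that entered the model, its emission values and its version are not given in the sources used here, and the state numbers carry no names. Per the file headers, a colour goes with each state, and 7 of the 11 colours are shared by 2 states. The deposited unit is a state number per segment, with no counts, coverage or scores, so the depth per sample is unknown and no interval or floor that needs depth is given. The map is 1 segmentation, tied to the wild-type H3.3 group by its file name only, with no column for a replicate or for the HIRA knockout. Library-level and knockout data were not used here.

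Segments were expanded to bins of 200 bp. The share of bases, the number and length of segments, and the borders between states were counted. Spread is given as SD over the 19 autosomes, which describes variation along the genome and not between animals. Genes came from the RefSeq table of GRCm38.p6, the assembly of mm10, with 1-based coordinates. Of 21900 protein-coding genes, 108 on the autosomes and X with a start within the first 3 Mb, which are unassembled there, and 13 on sequences outside the map were left out, leaving 21779. The table has no strand, transcripts or exons, and no genome sequence was used. The analysis fixed beforehand took 1 transcription start per gene; it was replaced by both ends of each gene record, and a gene was counted in a state when either end lay in it. A gene's ends thus mix promoters with 3′ ends.

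The fold of gene ends was the share of the 2 ends per gene in a state over the share of bases in it. It was set against 1000 circular shifts of the ends along each chromosome (two-sided, Benjamini-Hochberg over states, seed 20240). Hox regions ran from the first to the last gene record of a cluster with 5 kb on each side, without Hoxb13, which lies apart. Segments reached at either edge were kept whole, so the regions of HoxA, HoxB, HoxC and HoxD spanned 121.2, 108.6, 144 and 117 kb. The body fold was the share of gene body bases over the share of all bases. For 17 gene lists and 4 gene families, fixed before the data were examined, two-sided Fisher's exact tests compared members with all other protein-coding genes for each state, with Benjamini-Hochberg adjustment over 378 tests. Shares carry 95% Wilson intervals, which cover counting error only. Each list was also ranked among 10000 random lists of its size, matched on 10 classes of gene length. The 3 summary classes, chosen after the states had been seen, were states 3 to 6 at either end, states 9 to 11 at either end, and state 18 at both ends, adjusted over 63 tests, with 33 tests between pairs of lists.

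List symbols without a protein-coding record were left out: Ahsp; Mx1 and Mx2, held as pseudogenes; H3-3a and H3-3b, held under older symbols that are in the list; and H19, Meg3 and Kcnq1ot1, which are noncoding. Named genes followed a rule fixed beforehand. It took Hira, the first 4 members of each list in its most frequent state, the first 2 in another state, and the 10 genes with an end in the longest segments of states with an end fold of 5 or more. Other genes named were chosen after their values were seen. Some genes that the rule takes are not reported here.

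The list test was tested on simulated data with 21779 genes and lists of 30 genes. Null lists, of genes drawn at random over the genome, gave 0 calls in 378 tests. They were not drawn as clusters, so they cannot show how the test behaves for lists of neighbouring genes. Lists planted at 3 times the share of all genes were called in 57.1% of cases for state 3, 23.8% for state 9 and 85.7% for state 11. For state 18 that share would pass 100%, so it was capped, giving a median of 2.63 times. All of those lists (100%) were called. At 2 times the share the values were 0%, 0%, 14.3% and 66.7%, so lists of this size miss moderate differences in the rarer states.

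Alternatives were autosomes only, segments of 1 bin left out, the expanded file, the most frequent state within 1 kb, all annotated genes, genes within 100 kb counted once, and random lists not matched. Added after seeing the data were any bin within 1 kb of an end, any bin of the gene or 1 kb around it, genes of X and Y left out, lists matched on gene length, the summary classes, runs of states 3 to 6, symbol families with genes within 100 kb counted once, the erythroid list without globin genes and the housekeeping list without ribosomal protein genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.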

Results

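The series asked how HIRA, the chaperone that deposits histone variant H3.3 outside replication, shapes H3.3 in hematopoietic stem cells (HSCs) of adult mouse bone marrow. Its 6 libraries comprised 2 H3.3 ChIP libraries from wild-type cells, 2 from HIRA knockout cells and 1 input for each genotype. The values analysed were a single map of the mouse genome (mm10) into 18 chromatin states in bins of 200 bp, labelled by its file name as wild-type HSC H3.3. Only the file name ties this single map to that group, and which libraries or other tracks entered it is not given. It carries no read counts, no replicates and no knockout column. Its depth is thus unknown, and the comparison of wild-type with HIRA knockout H3.3 was not analysed here. The states carry numbers and no names, and are described below by where they lay. The map had 850831 segments over 2726.83 Mb, without gaps, and the dense and expanded versions gave the same state in 100% of bins. The only spread available was that along the genome, over the 19 autosomes, which are not biological replicates.

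A small part of the genome held a large part of the gene ends. States 3, 4, 5 and 6 together covered 1.13% of segmented bases and 24.9% of the ends of protein-coding genes, and 10372 of 21779 genes (47.6%) had either end in one of them. The fold of gene ends over the share of bases was 17.1 in state 3, 21.1 in state 4, 23.1 in state 5 and 27.3 in state 6. State 9, which covered 0.182% of bases, had a fold of 21.9. State 18 covered 55.0% of bases and was depleted of gene ends, at a fold of 0.44. Gene ends were also depleted in state 15 (fold 0.51) and state 14 (fold 0.65).

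Over the autosomes the end fold averaged 27 ± 6.57 (SD, 19 autosomes) in state 6 and 22.4 ± 5.75 in state 9. In 1000 circular shifts of the gene ends the fold of state 6 stayed between 0.80 and 1.90, and that of state 9 between 0.69 and 1.98. The two-sided shift p was 0.002, the smallest the shifts can give, for every state except 12 (0.282), 16 (0.024) and 17 (0.00999). The gene records carry no strand, so both ends of each gene were counted and the start of transcription could not be told from the 3′ end.

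**Figure D1:**
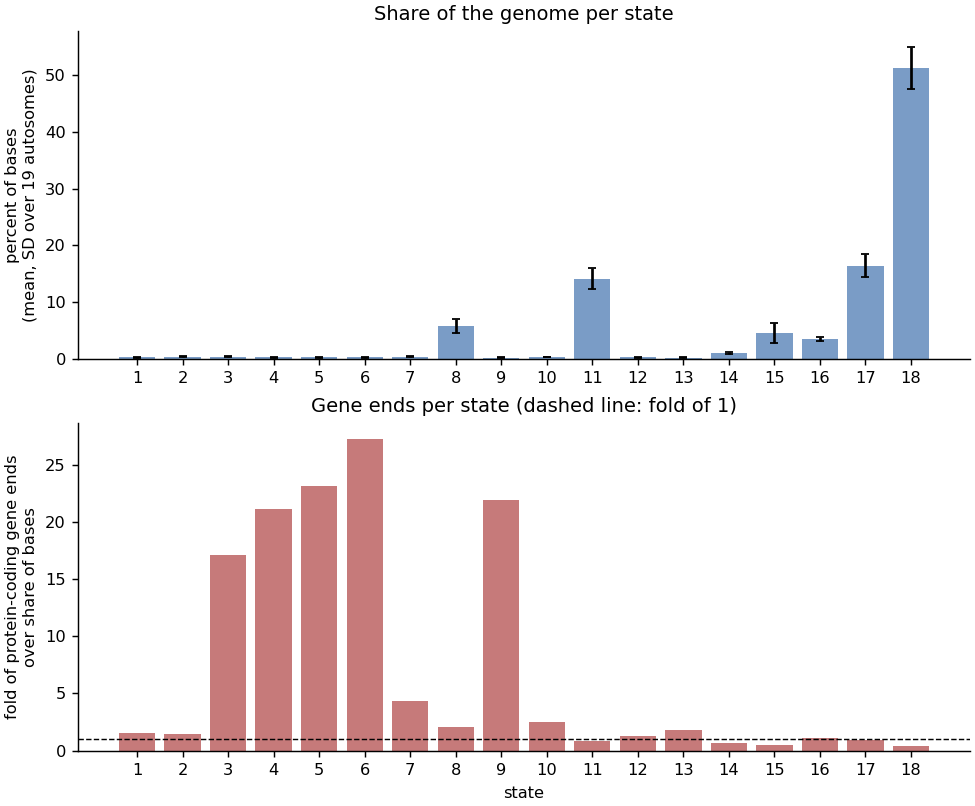
Percent of bases per state (upper panel, bars are means and error bars SDs over 19 autosomes) and fold of protein-coding gene ends over the share of bases (lower panel, all chromosomes). States 3 to 6 and 9 each cover under 1% of bases and have end folds of 17.1 to 27.3.

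Gene bodies, which made up 37.9% of segmented bases, were richest in states 8, 7 and 12, with body folds of 2.51, 2.43 and 2.15. State 8 formed the longest blocks of these: its longest segment spanned 76.2 kb at Trrap, a component of histone acetyltransferase complexes. States 11, 18, 14 and 15 were depleted in gene bodies, with folds of 0.80, 0.70, 0.50 and 0.44. State 11 covered 13% of bases in segments with a median of 2.40 kb, whereas the median segment of states 4, 5 and 6 was 0.40 kb.

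The states fell into neighbourhoods. State 3 bordered state 5 at 61.2% of its borders, and state 4 bordered state 6 at 62.6%. State 9 bordered state 11 at 61.2% and state 10 at 23.0% of its borders, and state 10 bordered state 11 at 79.5%. State 7 bordered state 8 at 66.7% of its borders, state 1 bordered state 16 at 58.4%, and state 15 bordered state 18 at 91.1%. Against the product of segment counts alone, these shares were 31.0 times for state 3 beside 5, 30.8 times for 4 beside 6, 15.9 times for 9 beside 10 and 8.87 times for 7 beside 8. The excess was smaller for 10 beside 11 (5.99 times), 1 beside 16 (5.00 times), 9 beside 11 (4.67 times) and 15 beside 18 (3.37 times), where the product alone would give 13.3, 11.7, 13.1 and 27%.

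**Figure D2:**
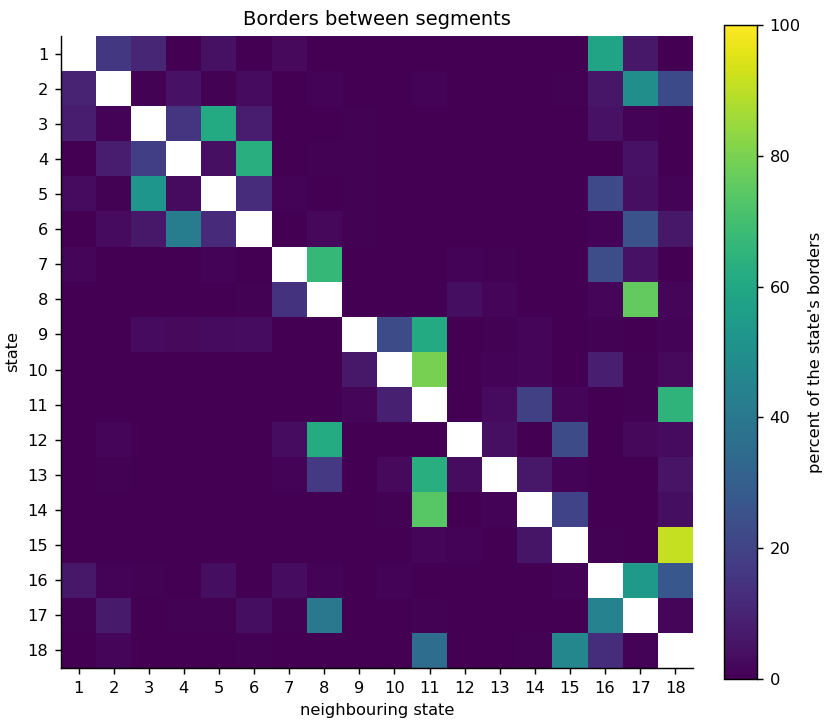
Percent of each state's borders (rows) that lie with each other state (columns). State 3 pairs with 5, state 4 with 6, state 9 with 10 and 11, and state 15 with 18.

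Genes that define the stem cell and genes of its mature progeny differed in their states. Of 34 HSC regulators and markers, 29 (85.3%, 95% Wilson interval 69.9 to 93.6) had an end in states 3 to 6, against 47.6% of other genes (Fisher's exact test, adjusted exact p = 2.36e-05). They included the transcription factor genes Gata2 (chromosome 6, 88193891 to 88207032, an end in state 5), Mecom, Runx1 and Hlf, each with an end in state 5, and Meis1 and Tal1, each with an end in state 3. Gfi1, a repressor that restrains HSC proliferation, instead had an end in a state 9 segment of 4.80 kb. State 5 alone held an end of 14 of the 34 genes (3.39 times the share of other genes, adjusted exact p = 0.000151), and state 7 an end of 7 (6.87 times, adjusted exact p = 0.000416). State 18 held an end of only 2 of the 34 genes, at 0.17 times the share of other genes (adjusted exact p = 0.00116).

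Far fewer mature lineage genes had an end in states 3 to 6. The share was 8 of 36 erythroid genes (22.2%), 1 of 24 neutrophil and monocyte genes (4.17%), 3 of 20 B cell genes (15.0%) and 2 of 23 T and NK cell genes (8.70%), each below other genes (adjusted exact p = 0.00481, 1.71e-05, 0.00634 and 0.000224). Set directly against the HSC list over 33 pair tests, the erythroid share was lower with an adjusted exact p of 1.03e-06, the neutrophil and monocyte share with 9.16e-09, the B cell share with 3.45e-06 and the T and NK cell share with 1.21e-07. Megakaryocyte genes, at 8 of 20 (40.0%), were also below the HSC list (adjusted exact p = 0.00577) but were not called against other genes (adjusted exact p = 0.557). No pair test of the erythroid list against another blood lineage list was called. When any bin within 1 kb of an end was counted, the erythroid share was 36.1% and the B cell share 35.0%, and neither was called against other genes (adjusted exact p = 0.105 and 0.244). With any bin of the gene or 1 kb around it the B cell share was 50.0% (adjusted exact p = 0.590). The grouping into states 3 to 6, states 9 to 11 and state 18 at both ends was chosen after the states had been seen.

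Among erythroid genes, Slc4a1, the anion exchanger of red cells, had both ends in state 18, and so had Hba-a1, an alpha globin gene whose near-identical copy makes its state uncertain. Gata1 on chromosome X had ends in states 17 and 18, and Klf1 had both ends in state 17. Epor, the erythropoietin receptor gene, had ends in states 8 and 16. State 18 held both ends of 9 of 36 erythroid genes (25.0%), against 0 of 34 HSC genes (adjusted exact p = 0.0124 between the lists) and 13.6% of other genes (adjusted exact p = 0.127). Of the 9, 4 were globin genes, and without the 7 globin genes of the list the share was 5 of 29 (17.2%, unadjusted exact p = 0.0169 against the HSC list). That p was not adjusted over the 33 pair tests. Among those, erythroid against megakaryocyte genes, at an unadjusted exact p of 0.0195 for this class, was not called (adjusted exact p = 0.0715). State 18 also held both ends of 5 of 24 neutrophil and monocyte genes (20.8%), called against the HSC list as well (adjusted exact p = 0.0383). That share was not called against other genes (adjusted exact p = 0.409). No single state was called for the erythroid, the neutrophil and monocyte or the T and NK cell list.

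Megakaryocyte genes were enriched in states 16 and 17. State 16 held an end of 9 of 20 (45.0%, 6.36 times the share of other genes, adjusted exact p = 3.43e-05) and state 17 an end of 11 (55.0%, adjusted exact p = 0.0391). State 17 also held an end of 50.0% of neutrophil and monocyte genes, 50.0% of B cell genes and 47.8% of T and NK cell genes, which were not called, and the lists were not tested against each other for these states. Pf4, the platelet factor 4 gene, had both ends in a state 16 segment of 5.20 kb, and Gp9, Gp5, Ppbp and Vwf each had an end in state 16. Itga2b, which encodes integrin alpha IIb, had ends in states 17 and 5. Mmrn1 had an end in a state 5 segment of 4.80 kb. Of the B cell genes, 5 of 20 had an end in state 2 (26.8 times the share of other genes, adjusted exact p = 1.07e-05), while Igll1 had both ends in state 17. Pax5, the B cell commitment factor, had both ends in state 11, Ebf1 had ends in states 9 and 4, and Gata3, a T cell regulator, in states 8 and 10. Of the myeloid regulators, Spi1 had ends in states 1 and 8 and Cebpa in states 9 and 11. Elane and Cebpe, expressed in granulocyte precursors, had both ends in state 17, Csf1r had ends in states 17 and 7, and Csf3r in states 16 and 17.

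**Figure D3:**
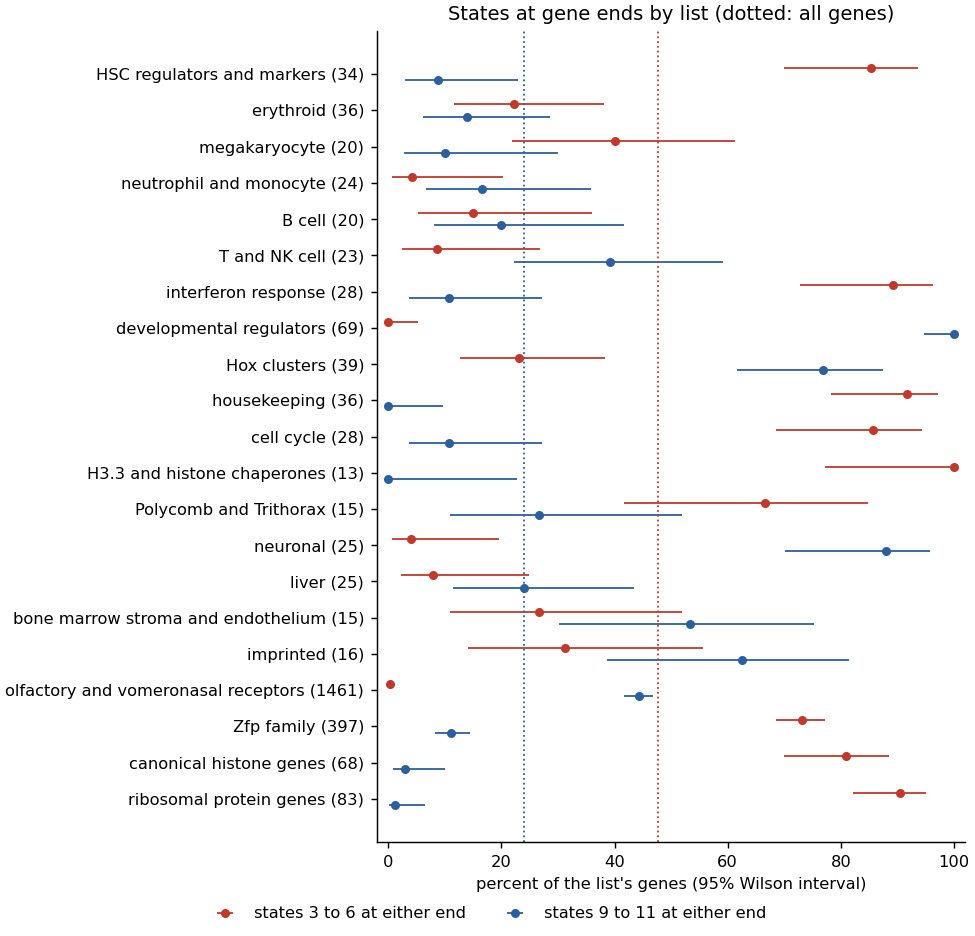
Percent of each list's genes (number of genes in parentheses) with an end in states 3 to 6 (red) or states 9 to 11 (blue), with 95% Wilson intervals that cover counting error only; dotted lines mark all protein-coding genes at 47.6% and 23.9%. HSC, interferon, housekeeping and cell cycle lists lie above 85% for states 3 to 6, and developmental regulators lie at 100% for states 9 to 11.

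Most interferon response genes, like most housekeeping genes, had an end in states 3 to 6. The mice of the libraries had received 2 doses of 20 ug of poly(I:C), an interferon inducer used to switch on the deletion. Their cells were sorted 7 days after the first dose. The signal tracks behind the map are not given, so it is unknown whether all came from such mice. Of 28 interferon response genes, 25 (89.3%) had an end in states 3 to 6 (adjusted exact p = 1.72e-05), among them Isg15, Irf7, Ifit2 and Oas1a with an end in state 3, and Ifit1 in state 4. State 3 alone held an end of 13 of the 28 (4.01 times the share of other genes, adjusted exact p = 4.29e-05). The share in states 3 to 6 was 33 of 36 (91.7%) for housekeeping genes, 24 of 28 (85.7%) for cell cycle genes and 75 of 83 (90.4%) for ribosomal protein genes, each above other genes (adjusted exact p = 1.26e-07, 0.000103 and 2.12e-15). The HSC list was not called apart from the housekeeping list (adjusted exact p = 0.741) or the interferon list (adjusted exact p = 0.961). No untreated mice were among the libraries, so no effect of poly(I:C) was measured.

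State 7 was enriched at the ends of housekeeping, ribosomal protein and cell cycle genes, besides those of the HSC list. It held an end of 16 of 36 housekeeping genes (15.0 times the share of other genes, adjusted exact p = 3.25e-14), 31 of 83 ribosomal protein genes (12.9 times, adjusted exact p = 1.38e-24) and 5 of 28 cell cycle genes (5.94 times, adjusted exact p = 0.00766). The housekeeping list shares 7 genes with the ribosomal protein list, 5 of them with an end in state 7, and without these 7 it had 11 of 29 genes in state 7 (12.8 times, unadjusted exact p = 3.50e-10). Tbp, Polr2a, Eef1a1 and Ppia each had 1 end in state 7 and the other in state 5 or 6. Actb and Gapdh had an end in state 5 with the other end in states 6 and 8. Mki67, Cdk1, Mcm2 and Aurka, all used by dividing cells, each had an end in state 6, and Top2a and Ccnb1 an end in state 5. Rpl11, Rpl12 and Rpl14 paired an end in state 8 with an end in state 6, 4 or 5, whereas Rpl10l, a testis-expressed copy, had both ends in state 15.

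All 13 genes of the H3.3 and histone chaperone list had an end in states 3 to 6 (adjusted exact p = 0.000163). Hira itself (chromosome 16, 18876750 to 18970309) had ends in states 3 and 8, Ubn1 in states 5 and 8, Cabin1 in states 8 and 3, Asf1a in states 6 and 7, and Chaf1a, a subunit of the replication-coupled chaperone, in states 4 and 8. Atrx on chromosome X had ends in states 18 and 6. Polycomb and Trithorax genes were not called, at 10 of 15 (66.7%, adjusted exact p = 0.246): Ezh2 and Eed had an end in state 5 and Suz12 and Rnf2 in state 6, while Ezh1 and Cbx2 had an end in state 9. Polycomb and Trithorax genes were called at 93.3% with any bin within 1 kb of an end (adjusted exact p = 0.00272) and at 100% with any bin of the gene or 1 kb around it (adjusted exact p = 0.000844). No single state was called for these lists.

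Regulators of other tissues occupied a separate set of states. All 69 developmental regulators had an end in states 9 to 11, against 23.7% of other genes (adjusted exact p = 1.64e-42), and 0 of 69 had an end in states 3 to 6. State 11 held an end of 55 of them (4.71 times the share of other genes), state 9 of 28 (5.21 times) and state 10 of 22 (22.6 times), with adjusted exact p of 1.85e-28, 1.32e-12 and 2.96e-22. Sox1 had ends in states 9 and 10, Nkx2-1 and Pax2 in states 10 and 11, Pax6 in states 11 and 18, and Neurog1 had both ends in a state 11 segment of 13 kb. Of 25 neuronal genes, 22 (88.0%) had an end in states 9 to 11 (adjusted exact p = 1.42e-10), including Snap25, Syt1, Gad1, Slc17a7 and Gad2, while Map2 had ends in states 5 and 18.

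Liver genes followed another course. State 18 held an end of 21 of 25 liver genes (2.45 times the share of other genes, adjusted exact p = 4.95e-06) and both ends of 12 (48.0%, adjusted exact p = 0.000103), among them Alb, Ttr and Fgb. Apoa1 had ends in states 17 and 4, and Apoa2 in states 6 and 17. Genes of bone marrow stroma and endothelium, cells that a sort for HSCs should exclude, had an end in states 9 to 11 in 8 of 15 cases (53.3%, adjusted exact p = 0.0232), with Col1a1 and Cxcl12 in state 11, Col1a2 in state 9 and Pdgfra in state 10. That share was no longer called with any bin of the gene or 1 kb around it (66.7%, adjusted exact p = 0.0505). Pecam1 had ends in states 16 and 1, and Cdh5 in states 17 and 18. Imprinted genes had an end in states 9 to 11 in 10 of 16 cases (62.5%, adjusted exact p = 0.00257), with Igf2 in state 11 at both ends, Dlk1 and Snrpn in states 11 and 18, and Peg3 in states 18 and 9. Mest had ends in states 11 and 8, and Igf2r in states 18 and 6.

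The 4 Hox clusters differed in their shares of states 3 to 6 and states 9 to 11. Of 39 Hox genes, 30 (76.9%) had an end in states 9 to 11 (adjusted exact p = 3.14e-11) and 9 (23.1%) an end in states 3 to 6. Hoxa10, with ends in states 5 and 9, counted in both classes, and Hoxa5, with ends in states 16 and 12, in neither. Genes with an end in states 3 to 6 lay within HoxA and HoxB: Hoxa3 had ends in states 8 and 3, and the HSC gene Hoxa9 had both ends in state 5. States 3 to 6 covered 25.9% of the HoxA region and 16.9% of the HoxB region, and 0% of the HoxC and HoxD regions. States 9 to 11 covered 40.8% of HoxA, 50.5% of HoxB, 99.7% of HoxC and 100% of HoxD. The rest of HoxA and HoxB lay in other states, such as 8, 16 and 17. Hoxa2, Hoxa11 and Hoxa13, toward the flanks of HoxA, and Hoxb1 each had an end in states 9 to 11, and Hoxb7 and Hoxb8 shared a state 9 segment of 5.40 kb. Counting genes within 100 kb once kept the first by position, which left 4 Hox genes in place of 39. Of these, 0% had an end in states 3 to 6, so that count cannot speak to genes further inside HoxA and HoxB.

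**Figure D4:**
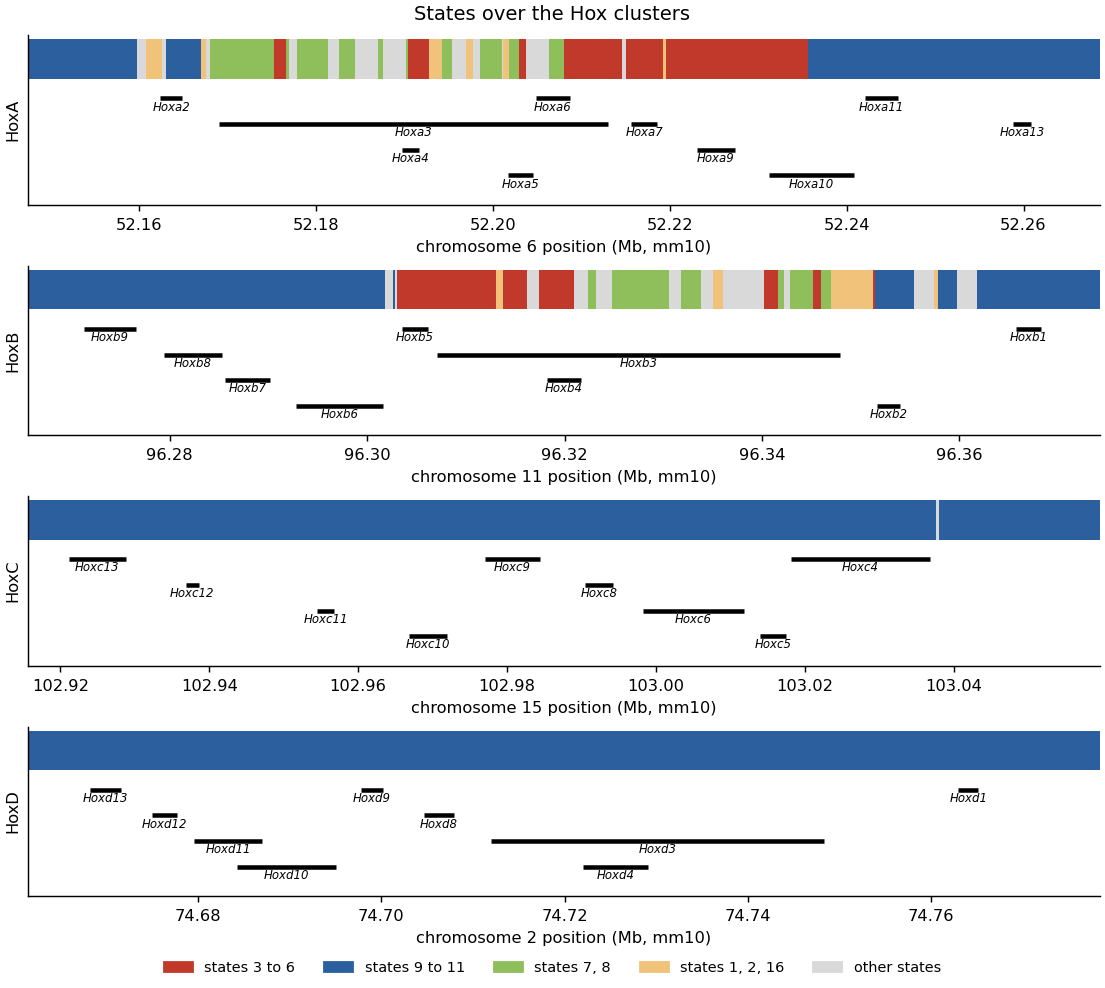
Chromatin states along the 4 Hox clusters (horizontal axes, position in Mb, mm10), with selected gene records below as black bars; red marks states 3 to 6, blue states 9 to 11. States 3 to 6 cover 25.9% of HoxA and 16.9% of HoxB and are absent from HoxC and HoxD.

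Large gene families had distinct states. Of 1461 olfactory and vomeronasal receptor genes, 4 had an end in states 3 to 6 (0.274%), while state 18 held an end of 994 (68.0%) and state 11 an end of 645 (44.1%, adjusted exact p = 1.51e-137). Olfr10 and Olfr1000 had both ends in state 18, and Olfr1008 had both in state 11. Zfp genes, which encode zinc finger proteins, had an end in states 3 to 6 in 290 of 397 cases (73.0%, adjusted exact p = 4.53e-24). State 12 held an end of 43 Zfp genes (10.8%), 30.9 times the share of other genes (adjusted exact p = 5.16e-43), and state 13 an end of 17 (6.45 times, adjusted exact p = 7.83e-08). Zfp101, Zfp108, Zfp11 and Zfp111 paired state 17 with an end in state 3, 4 or 5, Zfp1 had ends in states 3 and 8, and Zfp105 in states 9 and 18. Of 68 histone genes taken by symbol pattern, which admits replication-independent linker histones such as H1f0 and H1f10, 55 (80.9%) had an end in states 3 to 6 (adjusted exact p = 1.26e-07). State 3 held an end of 40 of them, 5.12 times the share of other genes (adjusted exact p = 2.46e-19), and H1f2 and H1f3 had both ends in it. With genes within 100 kb counted once, the histone share in states 3 to 6 was 60.0% of 10 genes and was no longer called (adjusted exact p = 0.622). Near-identical copies in these families make single members uncertain.

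Among states with an end fold of 5 or more, Tgif1, which encodes a transcriptional repressor, had an end in the longest state 3 segment (7.00 kb), and Arid5b and Arhgdib had ends in state 3 segments of 5.20 and 4.60 kb. Zfp503, Efna5 and Egr3 had ends in state 9 segments of 5.20, 5.00 and 4.80 kb. Across all 378 tests of a list against a state, 39 were called higher and 42 lower at an adjusted p under 0.05, and 104 had an unadjusted exact p under 0.05. Genes are not replicates, so each test states only whether a list was spread over the states of this 1 map like other genes.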

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

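The mitochondrial genome, which enters none of the gene comparisons, was divided between a pair of states. Of its 81 bins, 64 (79.0%) were in state 14 and 17 (21.0%) in state 15, against 0.923% and 4.56% of all segmented bases. It was singled out because it is a signal in sequence outside the comparisons. The map holds no control value, and no explanation, technical or biological, was tested.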

How the results depend on the processing

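No paired analysis was possible because the map is 1 segmentation, labelled wild-type by its file name, and has no column for a replicate. The summary classes, any bin within 1 kb of an end, any bin of the gene, the removal of X and Y genes and matching on gene length were chosen after seeing the data. Not run, for want of strand, transcripts or sequence, were assembly gaps in the denominator, the start shared by most transcripts, sequence content per state and random lists matched on CpG content. The share of bases stayed within 1 autosome SD in 36 of 36 values under autosomes only and segments of 1 bin left out. The expanded file holds the same state in 100% of bins, so its shares could not differ. The depth behind the states is unknown.

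Without segments of 1 bin, segments numbered 789368 in place of 850831, and those of states 4, 5 and 6 fell to 7333, 9866 and 10635. No state changed its most frequent neighbour, but all 18 border shares moved: to 61.4, 53.8, 56.4, 58.6, 53.7, 38.4, 73.3, 78.7 and 67.2% for states 1 to 9, and to 84.7, 66.4, 65.9, 66.1, 79.9, 93.8, 58.2, 46.1 and 47.4% for states 10 to 18.

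Of 54 end folds, 5 changed. With the most frequent state within 1 kb the fold crossed 1 in states 2, 16 and 17 (0.92, 0.90 and 1.04). The range of the shifts under this setting is not reported here. The side of 1 thus cannot be read as enrichment or depletion against the shifts. With all annotated genes the fold of state 17 also crossed 1 (1.05), but neither it nor that of state 13 (1.12) was called any longer. The cause of these changes was not tested. With all annotated genes, body folds moved to 1.84, 1.74, 2.04, 2.10, 0.57, 1.55 and 0.76 in states 4, 6, 7, 8, 15, 17 and 18.

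Of the 81 list calls, 77 were called the same way with the most frequent state within 1 kb, 81 without ends in segments of 1 bin, 79 with any bin within 1 kb, 78 with any bin of the gene, 78 without X and Y genes and 55 with genes within 100 kb counted once. With genes within 100 kb counted once, lower calls fell to 26. Hox genes in state 9 and histone genes in state 2 reversed, to -7.85 and -0.92 percentage points. These values rested on only 4 Hox and 10 histone genes, the first by position among neighbours. Higher and lower calls rose to 68 and 66 with any bin within 1 kb and to 82 and 105 with any bin of the gene, which count more states per gene. Of the 81 calls, 80 lay outside the central 95% of length-matched lists and 64 outside that of unmatched lists, where 17 calls of the large families had no value.

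Of 378 class values, 337 kept direction and side. With genes counted once, histone genes fell to 60.0% in states 3 to 6 and were 10.0% in states 9 to 11, both no longer called, and reversed to 20.0% for state 18 at both ends. Hox genes in states 3 to 6 (0%) were no longer called, nor was the 0% of Hox and interferon genes with state 18 at both ends. These values rested on 4 Hox and 24 interferon genes. The 0% of cell cycle genes, all 28 of which were kept, was not called either (adjusted exact p = 0.0514), and liver genes in states 9 to 11 reversed (21.7%). Liver also reversed with the most frequent state within 1 kb (24.0%), from a main value of 24.0% against 23.9% of other genes. Of class values that reversed, here and below, only histone genes with state 18 at both ends had been called in the main analysis.

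For state 18 at both ends, any bin within 1 kb and any bin of the gene required every bin counted to be in state 18. That is a stricter class, which fewer genes can meet. With any bin within 1 kb, erythroid (36.1%) and B cell genes (35.0%) in states 3 to 6 were no longer called. The 0% of HSC, Hox, cell cycle, housekeeping and interferon genes in the stricter state 18 class was not called either. Newly called were Polycomb and Trithorax genes in states 3 to 6 (93.3%), and chaperone (0%) and HSC genes (8.82%) in states 9 to 11. B cell genes with state 18 (10.0%), and Polycomb and Trithorax (26.7%) and neutrophil and monocyte genes (29.2%) in states 9 to 11, reversed. With any bin of the gene, B cell genes in states 3 to 6 (50.0%), stroma and endothelium genes in states 9 to 11 (66.7%) and the same 0% values were no longer called. Newly called were Polycomb and Trithorax genes in states 3 to 6 (100%), and chaperone (0%), HSC (17.6%) and interferon genes (10.7%) in states 9 to 11. B cell genes in states 9 to 11 (45.0%), T and NK cell genes with state 18 (8.70%) and imprinted genes in states 3 to 6 (62.5%) reversed. Without X and Y genes, HSC genes in states 9 to 11 (8.82%) and erythroid genes with state 18 at both ends (26.5%) were newly called, the 0% of cell cycle and interferon genes was not, and Polycomb and Trithorax genes in states 9 to 11 reversed (21.4%). The cause was not tested.

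The HSC list stayed above each blood lineage list in states 3 to 6, and was called, under all 6 list alternatives. The difference ranged from 52.1 to 63.1 percentage points for erythroid, 41.2 to 50.3 for megakaryocyte, 69.1 to 80.9 for neutrophil and monocyte, 44.1 to 80.3 for B cell and 63.7 to 78.3 for T and NK cell genes.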

Other observations

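The observations here, and all tests in this part, were chosen after the results had been seen. Several of the longest unbroken runs of states 3 to 6 lay over regulators of HSCs. The longest, of 16.0 kb each, touched Meis1 and the pair Hoxa9 and Hoxa10, whose products keep stem cells self-renewing, and the next touched Adgrg1 (14 kb), Gata2 (11.8 kb) and Nkx2-3 (11.6 kb). Bahcc1 and Tnrc18 (10.8 kb each), Bcl11a (10.4 kb) and the pair Rhof and Setd1b (10.2 kb) followed, which are not in the HSC list. Of the HSC list, Tal1 (9.40 kb), Etv6 (8.80 kb), Erg and Lmo2 (8.60 kb each) and Hlf (8.40 kb) came later, among runs of like length at Zfp608 (9.60 kb), Skil and Zfp36 (8.80 kb each) and others, 2 of which touched no protein-coding gene. The median of all 15998 runs was 1.80 kb. Of the 20 longest, 7 touched a gene of the HSC list, which 0.358% of all gene-touching runs did. The longest segments of state 1 lay at Fli1 (10.0 kb) and Msi2 (8.40 kb), that of state 7 at Meis1 (8.60 kb), and those of state 16 at Meis1 and Gse1 (9.60 kb each).

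Genes grouped by the letters of their symbol gave 143 calls of a higher share in 3978 tests over 221 families. Many of these families lie in clusters whose neighbours share segments, and with genes of a family within 100 kb counted once, a test added after seeing the data, 82 of the 143 calls held. State 9 held ends of Wnt genes (9 of 15 counted once) and Sema genes (8 of 19), which encode secreted and guidance signals, against 7.84 and 7.85% of other genes. State 15 held ends of Mup genes (4 of 6, against 3.66%). State 8 held ends of 19 of 28 Polr genes and 29 of 56 Eif genes, which serve transcription and translation, against 21.7% of other genes. State 6 held ends of 27 of the 56 Eif genes, against 15.8%. These were examples: Mrps, Dhx, Vps and Cox genes were also called in state 8, and Ube and Rab genes in state 6. The keratin (Krt) and Klk genes in state 11, the Ugt genes in state 15, the Clec genes in state 16 and the Defb genes in state 18 were called only with all genes counted, and fell to 4, 1, 5, 15 and 7 genes counted once. The clustered Pcdha and Pcdhga genes fell to 1 gene each and were not called.

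Chromosome X had another balance of states. Of 367 X gene ends in states 3 to 6, 69.2% lay in state 6 (95% Wilson interval 64.3 to 73.7), against 30.9% on autosomes, where single chromosomes ranged from 24.7 to 36.2%. If fewer expressed genes on X lowered only the number of ends in these states, their division would stay as on autosomes. The 69.2% lies outside the autosomal range (Fisher's exact p = 2.60e-49, which counts ends as independent). Whether expression also changes the division cannot be told, since the map holds no expression values. A local stretch is argued against by the lowest share over 5 equal parts of X, 62.9%. A single chromosome copy per cell may lower the signal on X, and all 4 Y gene ends in states 3 to 6 (Kdm5d, Eif2s3y, Uty and Ddx3y) also lay in state 6 (exact binomial test, one-sided, p = 0.00915). This rests on 4 ends, between positions 897566 and 1286628 of Y, which the test counts as independent. The labels used here do not give the sex of the mice, and no biological explanation was tested.

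The long runs at HSC genes were weighed against gene length, joined neighbours and general expression. The 29 HSC genes with a run had a median of 5.40 kb, above 100% of 10000 random lists matched on gene length. With runs that touch 1 gene only, the median of 26 HSC genes was 5.10 kb, again above 100% of lists. Housekeeping genes had a median of 3 kb, below the HSC list (permutation test, two-sided, p = 0.00032), and interferon genes 1.80 kb. Long runs were not confined to the HSC list: the Hox list, which shares Hoxa9 with it, had a median of 6.60 kb, and the housekeeping and ribosomal lists stood above 99.98% and 99.96% of length-matched lists. What sets run length stays open, since the tracks behind the states are unknown and no biological explanation was tested.

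The low share of erythroid genes in states 3 to 6 was weighed against misplaced ends and unusual genes. With any bin of the gene or 1 kb around it, 14 of 36 erythroid genes (38.9%) and 32 of 34 HSC genes (94.1%) met states 3 to 6 (Fisher's exact p = 7.31e-07). The erythroid share thus stayed low with the whole gene record counted. That argues against ends away from a promoter within the record as the whole cause of the low erythroid share. The count gives longer genes more bins and was not matched on gene length, so the size of the difference between the lists cannot be read from it. Without X-linked and globin genes the shares were 8 of 27 (29.6%) and 29 of 34 (85.3%), with an exact p of 1.45e-05. The lists were fixed beforehand but are small, and no biological explanation was tested.

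States that share a colour differed on X and beside state 16. States 1, 3, 5, 7 and 10 stood at 0.118, 0.123, 0.343, 0.038 and 0.0492 times their autosomal mean on X, and their partners 2, 4, 6, 8 and 11 at 0.502, 0.382, 1.09, 0.159 and 0.105 times. State 16 made up 58.4, 5.05, 22.1, 23.8 and 8.28% of the borders of the first 5, and 6.10, 0.192, 1.06, 1.56 and 0.330% of the borders of the partners. Of the remaining pairs, states 17 and 18 stood at 0.483 and 1.61 times on X, with 44.5 and 13.2% of borders with state 16. States 12 and 15 stood at 0.233 and 1.16 times on X, but their borders with state 16 ran the other way, at 0.256 and 0.766%. Chromosome Y was 99.5% state 18, most of it in 1 unbroken segment of 80166 kb. The 2 unplaced sequences of the map were 99.98 and 99.88% state 18. The map holds no coverage, so sequence to which few reads map cannot be told from state 18 here.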
